A study of Mus musculus with 2 samples.

How the data were processed

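The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against histone H3 trimethylated at lysine 9 (H3K9me3), a mark of silent chromatin. The tissue was whole stomach of mouse embryos of strain B6NCrl at day 15.5, with both sexes pooled. Per the labels, there was 1 group with 2 biological replicates. Replicate 1 pooled the stomachs of 78 embryos and had 2 technical replicates, and replicate 2 pooled 62 embryos and had 1 technical replicate. With no second tissue, stage or treatment in the series, the comparisons were between the replicates and between peaks and shifted copies of the same peaks.

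Per the file headers, the authors aligned the reads to mm10 and compared filtered alignments with control alignments. The aligner, the peak caller and their versions are not given in the sources used here. The authors deposited 4 lists: peaks called in each replicate alone, peaks called on both replicates together (the pooled list) and a replicated list. Each deposited peak has a fold over control at its summit, a ratio computed by the authors. Each deposited peak also has a −log10 p-value and a −log10 q-value against control, as the authors' peak caller wrote them. Fold values are the authors' throughout and were used to describe, rank and filter peaks within a list. Where a replicate's fold is given for a single replicated peak, it is the highest fold among that replicate's peaks that overlap it. Replicate means and SDs are over these highest values. The rule behind the replicated list is not given in the sources used here, so it was tested on the lists. All 1886 replicated peaks were identical to a pooled peak. All 1480 pooled peaks that overlapped a peak of both replicates by at least 50% of either peak were in the list, and 398 peaks of the list did not overlap a peak of both replicates. Of these, 215 overlapped a peak of replicate 1 only, 168 a peak of replicate 2 only and 15 a peak of neither.

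Total read numbers per library are not given in the sources used here. The depth behind each peak was therefore recovered from its fold and p-value, which fit a Poisson model with 1 added to pileup and control. Solving for both gave a whole number of ChIP fragments at the summit for 100% of peaks in each list, within a tolerance of 0.02. The median summit held 11 fragments in replicate 1, 10 in replicate 2, 17 in the pooled list and 22 in the replicated list. A count of 11 has an exact 95% Poisson interval of 5.49 to 19.7, which at the median control rate spans a fold of 1.54 to 4.92. A count of 22 has an interval of 13.8 to 33.3, or a fold of 2.04 to 4.73. The commonest control rate at a summit was 3.21 fragments in replicate 1, 2.76 in replicate 2 and 6.05 in the pooled and replicated lists. Intervals on counts and shares cover counting error only.

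Coordinates were set against the GRCm38 reference sequence and the GENCODE M21 annotation, which are the build the files use. Only the 21 assembled chromosomes entered the tests. Peaks on unplaced and unlocalized scaffolds were counted and left out, because no table linking the scaffold names of the files to the reference was used here. Coordinates are given counting from 1.

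Peaks counted as shared when they overlapped by at least 1 bp. Chance was measured by shifting all peaks of a chromosome together along it, in a circle, by a random distance, after runs of at least 1000 unknown bases had been taken out. Such a shift keeps the spacing of peaks and the order of genes. The overlap of replicates was tested one-sided with 1000 shifts, of which the smallest p is 0.000999. Gene lists and gene positions were tested two-sided with 1000 shifts, of which the smallest p is 0.00200, and sequence shares with 200 shifts, of which the smallest p is 0.00995. Benjamini-Hochberg adjustment ran over the 17 gene lists and over the 4 position classes, with a threshold of 0.05. A gene counted as overlapped when a peak touched its body or the 2 kb upstream. The lists were the C2H2 zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, beta-defensin and major urinary protein, Rhox, Xlr and Mage, histone, ribosomal protein, imprinted and germline genes, regulators of stomach and foregut, stomach products, neural regulators, genes of muscle, blood and immune cells, genes of liver, pancreas and intestine, and repressive chromatin machinery. Position classes were assigned by the peak midpoint in the order transcription start (within 2 kb), exon, intron and between genes. Shares on chromosomes were compared with chromosome length by exact 95% binomial intervals. Soft-masked bases, which mark interspersed and simple repeats, and G and C bases were counted per peak. The share of 32-base words of a peak that occur again on the assembled chromosomes measured how far its sequence is repeated.

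The lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. Named were the protein-coding genes at the 10 replicated peaks of highest fold, up to 4 genes per list with the highest fold, the 5 windows of 1 Mb with the most replicated peaks and up to 3 genes in each (with a tied window kept), and the widest peak with its gene. The alternatives were stricter overlaps, a −log10 q of at least 2, equal list lengths, autosomes only, each replicate left out in turn, the pooled list, the upper 50% of peaks by fold, peaks placed singly at random, other gene windows, Fisher's exact test and each peak counted for 1 gene. Leaving out peaks of high control rate, leaving out the densest 1 Mb window of each chromosome and keeping only peaks found in both replicates were added later.

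The tests were tested on simulated data. With 30 or 80 of the replicated peaks moved into zinc finger genes, the list passed at an unadjusted p in 20 of 20 simulations. With 0 moved it passed in 2 of 20, and the other lists did so in 0.625% of 320 tests. The 4 position classes were called, unadjusted, in 6 of 80 tests with 0 moved, in 2 of 80 with 30 moved and in 8 of 80 with 80 moved. A planted overlap of 10% of replicate 1 peaks was measured as 10.3%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.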

Results

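H3K9me3, a histone mark of silent chromatin, was mapped in stomachs of day 15.5 mouse embryos, in 2 biological replicates of pooled embryos. The lists held 14566 peaks in replicate 1, 19920 in replicate 2, 20307 in the pooled list and 1886 in the replicated list. The replicated peaks covered 924092 bp and had a median length of 402 bp, against 212 bp in replicate 1 and 201 bp in replicate 2. Enrichment was modest in every list. The median fold over control was 2.85 in replicate 1, 2.91 in replicate 2 and 2.87 in the replicated list, with maxima of 6.0, 6.03 and 5.46. Of the replicated peaks, 70.7% had a q-value of 0.05 or less, against 9.21% in replicate 1 and 6.35% in replicate 2.

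The first comparison asked how far the replicates marked the same places. Few peaks were shared, but far more than shifted peaks would share. Of 14343 replicate 1 peaks on chromosomes, 1394 overlapped a replicate 2 peak, or 9.72% (95% exact binomial interval 9.24 to 10.2), against a mean of 0.386% for shifted peaks. In the other direction, 1404 of 19714 replicate 2 peaks were shared, or 7.12% (6.77 to 7.49), against 0.279%. The ratios to the shifted means were 25.2 and 25.5, and each had a one-sided permutation p of 0.000999, the smallest that the shifts can give. Sharing rose with strength, from 6.91% of the replicate 1 peaks ranked below 5000 to 28.4% of the strongest 1000 and 40.2% of the strongest 500. With a −log10 q of at least 2 in both lists, 24.9% of replicate 1 peaks and 30.2% of replicate 2 peaks were shared. When an overlap had to reach 50% of both peaks, the shares were 5.15% and 3.75%. Without peaks whose control rate was at least 3 times the commonest, they were 8.63% and 6.27%. How far such peaks carry the rise with strength was not tested.

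**Figure D1:**
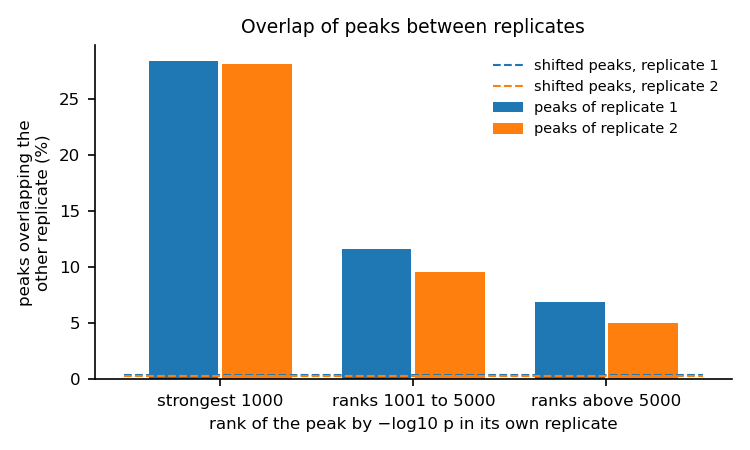
Bars show the percentage of peaks that overlap a peak of the other replicate (y axis), by rank of the peak in its own replicate (x axis), for replicate 1 (blue) and replicate 2 (orange), and dashed lines show the mean for shifted peaks. Sharing is 28.4% and 28.2% among the strongest 1000 peaks and 6.91% and 5.04% below rank 5000, all above the shifted means of 0.386% and 0.279%.

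Over the 1394 pairs of shared peaks, fold in replicate 1 and in replicate 2 had a Spearman rho of 0.312 and a Pearson r of 0.450 on the log2 scale. These are correlations across peaks, which are not independent replicates, so no p is given. The log2 ratio of the folds had an SD of 0.31. The rho was 0.906 over the 91 pairs with a −log10 q of at least 2 in both. How many of these pairs stood on a high control rate was not counted. Median fold was similar in peaks that overlapped the replicated list and in the rest. Replicate 1 peaks that overlapped a replicated peak had a median fold of 2.92, against 2.85 for the rest, and in replicate 2 the medians were 2.92 and 2.91. Upper quartiles were further apart, 3.33 against 3.09 in replicate 1 and 3.38 against 3.17 in replicate 2. Length differed more, with medians of 274 bp against 207 bp in replicate 1 and 255 bp against 198 bp in replicate 2.

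Several of the 10 strongest replicated peaks lay in or near zinc finger genes. The highest fold, 5.46, was at chromosome 4, 146480409 to 146481006 (mm10), 10116 bp outside Zfp992, with a mean of 5.42 ± 0.876 over the replicate lists (SD, n = 2). Zfp37 had a peak on a coding exon (chromosome 4, 62191179 to 62191602) with fold 5.39 and a replicate mean of 5.14 ± 0.127 (SD, n = 2). Zfp68 held 2 of the 10 strongest, in an intron (chromosome 5, 138609480 to 138609781, fold 5.10) and in the 3′ UTR (138605588 to 138606137, fold 4.92). AU041133 had fold 4.97 on a coding exon (chromosome 10, 82150976 to 82152385), and Zfp936 had 4.96 in an intron (chromosome 7, 43165703 to 43166361). Klf14, a Krüppel-like factor gene outside the fixed zinc finger list, was covered by a peak of 2245 bp (chromosome 6, 30956499 to 30958743, fold 4.77) that had fold 5.08 in both replicates. Asmt, the last enzyme of melatonin synthesis, had an intronic peak of fold 4.83 (chromosome X, 170674568 to 170675310), with 3.09 in replicate 1 and 5.85 in replicate 2. Mid1, a ubiquitin ligase gene, had a peak of fold 4.86 on a coding exon (chromosome X, 169988504 to 169989556). All of its 32-base words (100%) occur again on the assembled chromosomes, and its control rate was 16.5.

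Zinc finger genes of the C2H2 class, a large family of DNA-binding proteins, were the group most often overlapped in number. Replicated peaks overlapped 69 of 465, or 14.8%, against a mean of 9.13 for shifted peaks and against 2.24% of all other genes. The ratio to the shifted mean was 7.56 (two-sided permutation p = 0.00200, adjusted p = 0.0170). In the larger lists the zinc finger ratio was smaller, 2.11 without replicate 2, 1.72 without replicate 1 and 2.03 in the pooled list, and the list still passed. With each peak placed at random on its chromosome, which breaks up clusters, the zinc finger ratio was 4.92 and the list passed. All 69 were among the 394 genes named Zfp, and 0 of the 71 with other names were overlapped. For the 41 genes with the stem Zbtb the shifted mean was 0.962 (permutation p = 0.737), so a count of 0 there did not differ detectably. The 174 peaks in these genes had a median fold of 3.12, against 2.92 over all 1746 replicated peaks on chromosomes. A control rate of at least 3 times the commonest stood under 4 of the 174 and 178 of the 1746. How far this makes the difference in fold was not tested. Among the 69 genes, 38 held 2 or more of the 174 peaks. Of these peaks, 73 lay on coding exons, 69 in introns and 17 in 3′ UTRs. Zfp981 held 12 peaks and Zfp873, picked out after its count was seen, held 9. Zfp180 had a peak of 3294 bp on a coding exon (chromosome 7, 24104244 to 24107537) with fold 4.62 and a replicate mean of 4.49 ± 0.595 (SD, n = 2). Repeated sequence was scarce in these peaks, with a median of 0.708% of 32-base words occurring again. Counted only within 2 kb of a transcription start, 4 zinc finger genes were overlapped, and the call was lost (ratio 2.40, adjusted p = 0.926 by permutation).

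**Figure D2:**
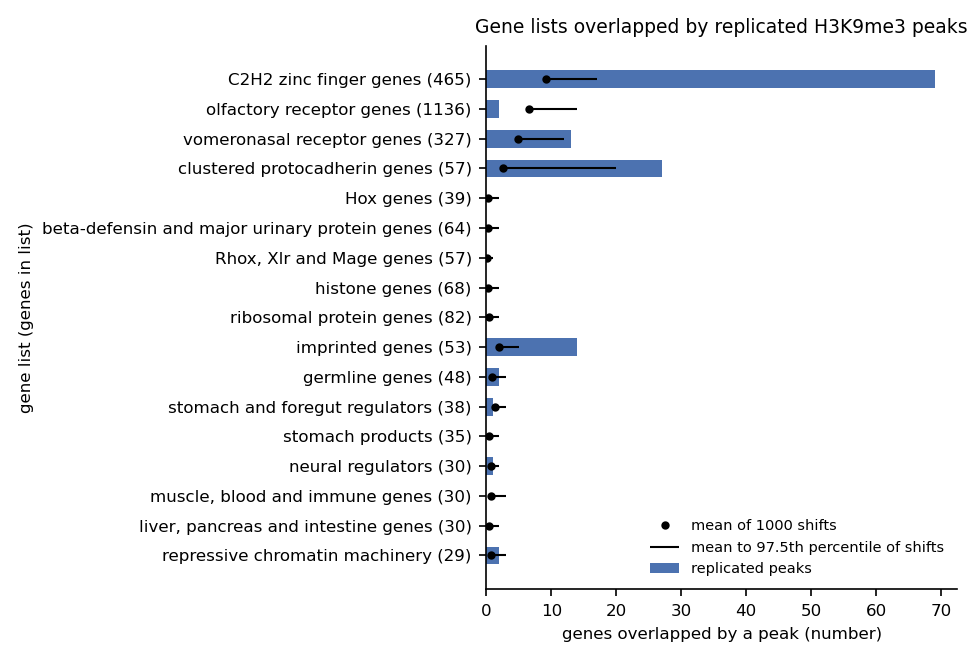
Bars show how many genes of each fixed list (y axis, list size in brackets) a replicated peak overlaps, black points show the mean of 1000 shifts, and black lines run to the upper end of the central 95% of shifts. Zinc finger genes (69 against 9.13) and imprinted genes (14 against 1.90) passed the adjusted test, and protocadherin genes (27 against 2.5) did not.

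Clustered protocadherin genes, which code for cell adhesion proteins of neurons, had the highest share of overlapped members. A replicated peak overlapped 27 of 57 genes, or 47.4%, against a mean of 2.5 for shifted peaks (ratio 10.8). The permutation p was 0.0180 and the adjusted p 0.102, so the list did not pass. The genes form 1 locus, and shifts that met it gave as many as 20 genes at the upper end of the central 95%. By permutation, the protocadherin list passed in the pooled list with a smaller ratio (2.34, adjusted p = 0.0340) and without replicate 1 (1.92, adjusted p = 0.0408), but not without replicate 2 (2.35, adjusted p = 0.0509). It also passed within 2 kb of transcription starts, where 17 genes were overlapped (ratio 84.2, adjusted p = 0.0340, permutation). The 47 peaks had a median fold of 3.12. The strongest lay at chromosome 18, 37722673 to 37723358, in introns of Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 and other gamma genes, with fold 4.83, and 4.52 in each replicate. The same peak lies in the long gene models Gm42416, Gm37013 and Gm37388, which span the locus. Gene models of the gamma cluster all run to the same last exons, so 1 peak counts for several genes, and Pcdhga1 alone holds 41 of the 47. Counted for 1 gene each, the peaks overlapped 1 protocadherin gene on the list. In that count a peak wholly inside several genes goes to the gene that starts first, such as Gm42416, which is off the list. The count of 1 follows from that rule and does not measure how many protocadherin genes are marked. With each peak placed at random, the protocadherin ratio was 4.63 and the list did not pass.

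**Figure D3:**
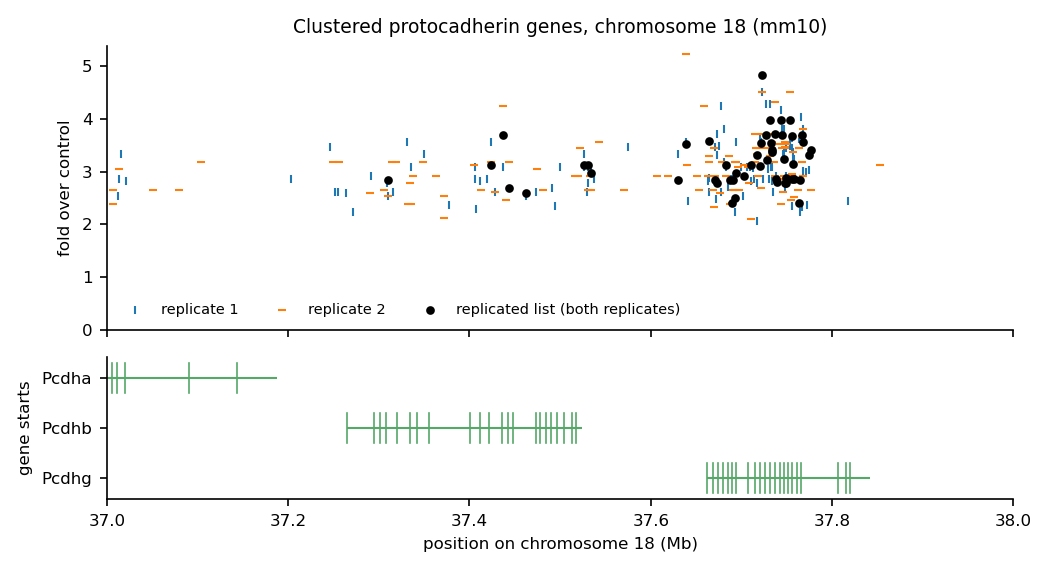
The upper panel plots fold over control (y axis) of peaks against position on chromosome 18 in Mb for replicate 1 (blue), replicate 2 (orange) and the replicated list (black), and the lower panel marks the starts of alpha, beta and gamma protocadherin genes. Most of the 51 replicated peaks lie over the gamma genes, where the strongest has fold 4.83.

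Imprinted genes, which are expressed from 1 parental allele, were also overlapped more often than by shifted peaks. Replicated peaks overlapped 14 of 53, or 26.4%, against a shifted mean of 1.90 (ratio 7.35, permutation p = 0.00200, adjusted p = 0.0170). The genes were Mest, Grb10, Gnas, Nespas, Kcnq1, Kcnq1ot1, Impact, Snrpn, Snurf, Blcap, Nnat, Peg3, Usp29 and Meg3. Some are overlapping or neighbouring genes that share a peak, and the 14 genes held 18 peaks. Mest had the highest fold, 3.83, in an intron (chromosome 6, 30737246 to 30737792), with 2.44 in replicate 1 and 4.25 in replicate 2. Grb10, a growth factor receptor adaptor gene, had a peak of 1290 bp at a 5′ UTR exon (chromosome 11, 12025645 to 12026934, fold 3.52) with a replicate mean of 3.79 ± 0.327 (SD, n = 2). Gnas and its antisense gene Nespas shared a peak of fold 3.37 (chromosome 2, 174297021 to 174297433), with a replicate mean of 3.12 ± 0.0351 (SD, n = 2). The imprinted ratio was smaller, though the list passed, without replicate 2 (2.29), without replicate 1 (2.05) and in the pooled list (2.36). With each peak counted for 1 gene, 9 imprinted genes were overlapped (ratio 5.36), and within 2 kb of transcription starts 7 were (ratio 37.8), each with a permutation adjusted p of 0.0340. In the upper 50% of peaks by fold, 6 imprinted genes were overlapped and the call was lost (ratio 5.26, adjusted p = 0.113 by permutation).

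Receptor genes of the chemical senses did not pass in the replicated list. Replicated peaks overlapped 13 of 327 vomeronasal receptor genes against a shifted mean of 4.83 (ratio 2.69, permutation p = 0.0260, adjusted p = 0.110). The vomeronasal list passed without replicate 2 (61 genes, ratio 1.89, adjusted p = 0.0340) and without replicate 1 (68 genes, ratio 1.55, adjusted p = 0.0226), but not in the pooled list (67 genes, ratio 1.61, adjusted p = 0.0934), all by permutation. The strongest were in introns of Vmn2r75 (chromosome 7, 86154926 to 86155244, fold 3.69), Vmn2r55 (fold 3.41) and Vmn2r102 (fold 3.12) and on a coding exon of Vmn1r65 (fold 3.58). Only 2 of 1136 olfactory receptor genes were overlapped, Olfr362 and Olfr839-ps1, each by a peak of fold 2.81 that met no replicate 1 peak, against a shifted mean of 6.52 (ratio 0.307, permutation adjusted p = 0.577). Fisher's exact test treats neighbouring genes as independent and takes no account of gene length. By Fisher's exact test, olfactory receptor genes were called as overlapped less often (adjusted p = 5.73e-10) and protocadherin genes as overlapped more often (adjusted p = 1.87e-27). For olfactory receptors it set 0.176% of genes against 2.63% of other genes, a ratio of 0.0669. The shifts keep gene lengths and gave 0.307, so that call cannot be told apart from an effect of gene length.

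Genes of the stomach and of other cell types did not differ detectably from shifted peaks in the replicated list. Of 38 regulators of stomach and foregut, 1 was overlapped, the growth factor receptor gene Fgfr2, by an intronic peak of fold 2.84 (chromosome 7, 132907424 to 132907718), against a shifted mean of 1.31 and 2.51% of other genes. None of the 35 stomach products found in the annotation was (0, against a shifted mean of 0.387). Of 30 neural regulators, 1 was overlapped, Rbfox3, by an intronic peak of fold 3.12 with 2.30 in replicate 1 and 3.72 in replicate 2 (shifted mean 0.669). The neural list passed without replicate 1 (ratio 2.01, adjusted p = 0.0408 by permutation) and turned below shifted peaks without replicate 2 (0.495). The count was 0 for the 30 muscle, blood and immune genes and for the 30 genes of liver, pancreas and intestine. It was also 0 for 39 Hox genes, 64 beta-defensin and major urinary protein genes, 57 Rhox, Xlr and Mage genes, 68 histone genes and 82 ribosomal protein genes. Shifted means for these 7 lists were all below 1, so an overlap below chance was not detectable. Of 48 germline genes, 2 were overlapped, both near their starts. They were Dazl (chromosome 17, 50293442 to 50293891, upstream, fold 3.32) and Ddx4 (chromosome 13, 112651931 to 112652278, first part of the gene, fold 3.41), which act in germ cell development (shifted mean 0.824, permutation adjusted p = 0.951). Of 29 genes of repressive chromatin machinery, 2 had an intronic peak, Atf7ip (fold 3.41) and Smchd1 (fold 3.31), against a shifted mean of 0.781 (permutation adjusted p = 0.951).

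Some regions held many replicated peaks, though most of the 1746 on chromosomes lay elsewhere. The 1 Mb window with the most, 51, was the protocadherin locus at 37 to 38 Mb of chromosome 18. Next came 147 to 148 Mb of chromosome 4 with 41 peaks and 9 zinc finger genes, among them Zfp982 (fold 3.63), Zfp933 (3.10) and Zfp979 (2.67). The neighbouring window at 146 to 147 Mb held 25 peaks, with folds of 3.58 in Zfp992 and 3.48 in Zfp981. Chromosome 7 at 12 to 13 Mb also held 25, of which 6 were in Zfp606 (fold 4.4), 4 in Zfp329 (4.26) and 8 in Zfp110 (3.83), and the vomeronasal receptor gene Vmn2r55 lies there as well. Chromosome 17 at 13 to 14 Mb held 25 as well, with folds of 3.22 at Smok2a and 2.66 at Smok2b, which are kinase genes. The third window by number, 88 to 89 Mb of chromosome 1, had the lowest median fold of these, 1.96 over 40 peaks, and 39 of the peaks lay within 99.3 kb (88211454 to 88310732) with a median control rate of 35.2, which is 5.83 times the commonest rate. The block spans Mroh2a (fold 2.42), the 3′ part of the Ugt1a genes Ugt1a9 and Ugt1a10 (fold 2.40), which code for detoxifying enzymes, Hjurp and Trpm8. Smaller blocks with a control rate of at least 3 times the commonest lay in the windows of chromosomes 4, 7 and 17. The one on chromosome 7 was 1 peak, at 9.21 times. The largest held 8 peaks at chromosome 4, 147417185 to 147432432 (4.93 times), 6 at Zfp981 and Zfp992 (3.81 times) and 6 at chromosome 17, 13540483 to 13552389 (3.37 times). The widest replicated peak, 4239 bp at chromosome 13 (119613466 to 119617704), lay 2406 bp outside Tmem267, with fold 2.21 and a control rate of 85.3.

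**Figure D4:**
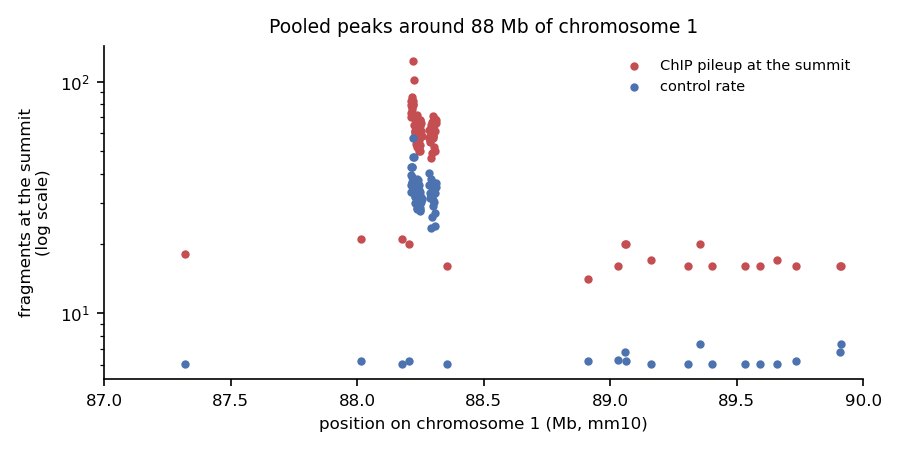
ChIP pileup at the summit (red) and control rate (blue), in fragments on a log axis, are plotted for pooled peaks against position on chromosome 1 in Mb. The 71 peaks inside the block have a median control rate of 33.5, and the 19 peaks outside it between 87 and 90 Mb have a median of 6.25.

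Relative to genes, replicated peaks were found more often than shifted peaks on exons and near transcription starts. Exons held 163 of 1746 peaks, or 9.34% (95% exact interval 8.01 to 10.8), against 2.41% for shifted peaks (permutation, adjusted p = 0.00400). Peaks in zinc finger genes included 73 on coding exons and 17 in 3′ UTRs, so part of this excess may be that result again. No run left those genes out. Within 2 kb of a transcription start lay 191 peaks, or 10.9% (9.51 to 12.5), against 7.31% (permutation, adjusted p = 0.00400). Introns held fewer, 26.4% against 32.9% (permutation, adjusted p = 0.0107), and the 53.3% between genes did not differ detectably from 57.4% (adjusted p = 0.152). The size of these shares depended on the list. Exons held 3.44% in replicate 1 alone, 3.63% in replicate 2 alone and 3.42% in the pooled list, all above shifted peaks. The share near starts was 5.33% in replicate 1 and 6.23% in the pooled list, both below their shifted peaks, and 7.58% in replicate 2, which did not pass.

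Replicated peaks were poorer in soft-masked repeats and richer in G and C than shifted peaks. The mean soft-masked share per peak was 27.8%, against 34.0% for shifted peaks (two-sided permutation p = 0.00995). The mean GC share was 46.3%, against 42.1% (two-sided permutation p = 0.00995). Without replicate 2, the GC difference of 4.18 points became 1.5 points. Without replicate 1, the soft-masked share was 24.4% against 33.7%. The smallest p of 200 shifts is 0.00995. The replicates differed in GC, with means of 43.5% in replicate 1 and 46.6% in replicate 2. Repeated sequence was counted without a test. In 0.401% of replicated peaks more than 90% of 32-base words occurred again, against 6.22% of shifted peaks, while the median share of such words was 1.81% in replicated peaks and 0% in shifted peaks. Shifts avoided only long runs of unknown bases, so shifted peaks could land on such repeated sequence, where replicated peaks were rare. How far this makes the soft-masked and GC differences was not tested, and the other comparisons with shifted peaks share the limit.

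Chromosomes differed in density around a mean of 0.659 replicated peaks per Mb. Shares were above the share of length on 6 chromosomes, below it on 9 and within the interval on 6. The densest were chromosome 17 with 1.38 peaks per Mb and chromosome 7 with 1.37, followed by chromosome 4 with 1.2 and chromosome 18 with 1.11. The intervals treat peaks as independent, which clusters are not. With the densest 1 Mb window of each chromosome left out, chromosomes 17, 7, 4, 13 and 5 stayed above their share of length. Chromosome 18, which lost 51 of its 97 peaks with the protocadherin window, then had 0.532 per Mb and lay within the interval. Chromosomes 2, 12 and 19 then came within it from below, and chromosome 1 fell below it. Chromosome X had 37 peaks, or 0.226 per Mb and 2.12% of all (1.5 to 2.91) on 6.18% of the length. Chromosome Y had 6 peaks, or 0.0681 per Mb. Embryos of both sexes were pooled, so X and Y were present in fewer copies than autosomes. How far this makes the low densities on X and Y was not tested.

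**Figure D5:**
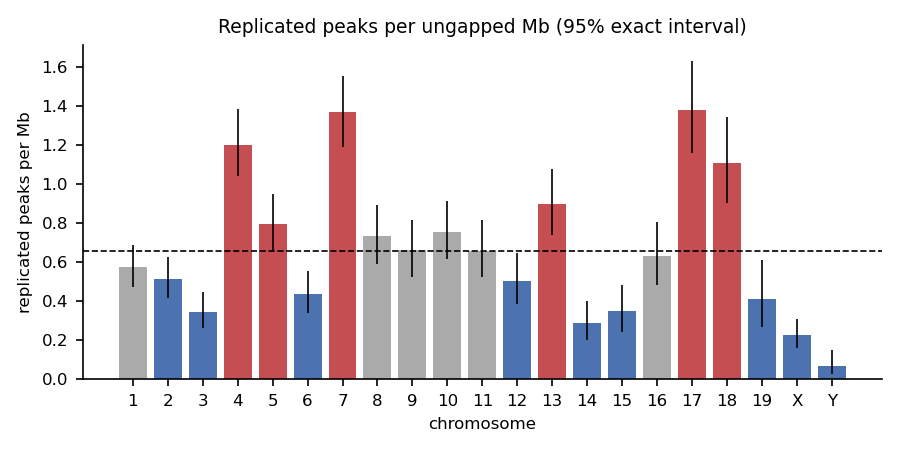
Bars show replicated peaks per ungapped Mb (y axis) on each chromosome (x axis) with 95% exact binomial intervals, and the dashed line is the mean of 0.659. Red marks the 6 chromosomes above their share of length, blue the 9 below and grey the 6 within the interval.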

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

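Of the tests in this part, the one on control rates was chosen after the result was seen. Peaks were found in data that the comparisons leave out. Scaffolds that are not placed on a chromosome held 140 of the 1886 replicated peaks, or 7.42% (95% exact binomial interval 6.28 to 8.70). That is 26.2 peaks per Mb, against 0.659 on chromosomes. In the replicate lists scaffolds held 1.53% and 1.03% of peaks. The 140 peaks lay on 15 scaffolds, 40 of them on 1.

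Scaffold peaks stood on deep coverage. The median control rate under replicated scaffold peaks was 21, against 6.25 under replicated chromosome peaks, a ratio of 3.36. This is consistent with repeat sequence that the assembly holds in fewer copies than the animals do, which raises ChIP and control alike. Deeper coverage also lets a smaller fold pass, and the median fold of scaffold peaks was 2.40, against 2.92. Whether depth alone admits them was not decided, since 49.3% of scaffold peaks (69) reached a fold of 2.41, the 5th percentile for chromosome peaks of common control rate. No biological explanation was tested, because the design has 1 group.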

How the results depend on the processing

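Alternatives that left out peaks of high control rate or the densest window of each chromosome, or kept only peaks found in both replicates, were chosen after the data were seen, and the others before. Both overlap shares passed under every alternative run, from 5.15% to 24.9% for replicate 1 and from 3.75% to 30.2% for replicate 2. The soft-masked and GC differences kept their direction and passed with each replicate left out, in the pooled list, in the upper 50% of peaks by fold and with peaks placed at random. The GC difference fell from 4.18 to 1.5 points in replicate 1 alone. Exons and introns also passed in these settings and without peaks of high control rate. Exon shares were 3.44% in replicate 1 alone, 3.63% in replicate 2 alone and 3.42% in the pooled list. The number of replicated peaks was 20307 in the pooled list and 974 at a −log10 q of at least 2, and the bases covered were 5373512 and 528413. With 1 replicate left out these ranged from 14566 to 19920 peaks and from 3550370 to 4547684 bp, since a single list has no replication step. Spearman's rho was 0.372 with overlaps of 50% of both peaks and 0.906 at a −log10 q of at least 2, and the cause was not tested. Of 17 lists, 2 passed in the main test, 1 in the upper 50% of peaks by fold, 4 by Fisher's exact test, and 3 to 5 with 1 replicate left out. The 3 in replicate 1 alone were zinc finger, imprinted and vomeronasal genes, and replicate 2 alone added protocadherin and neural genes. The number of chromosomes off their share of length was 12 to 18, against 15. Peaks placed at random on their chromosomes were not run for chromosome shares, which they leave fixed.

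Directions turned as follows, and the cause was not tested. Among peaks, the share within 2 kb of a transcription start turned in replicate 1 alone (5.33%, against 7.58% in replicate 2 alone, which kept its direction but did not pass) and in the pooled list (6.23%), and the share between genes in replicate 1 alone (63.3%), in replicate 2 alone (59.3%) and in the pooled list (63.1%). The share between genes, which did not pass in the main test, passed in the same direction in the upper 50% of peaks by fold and with peaks placed at random, and in the opposite direction in each replicate alone and in the pooled list. For gene lists, the ratio to shifted peaks crossed 1. In replicate 1 alone it was 1.04 for olfactory receptors, 1.11 for Hox, 0.747 for germline (1.47 in replicate 2), 0.495 for neural (2.01 in replicate 2, where the list passed) and 0.646 for repressive chromatin genes. In replicate 2 alone it was 1.00 for olfactory receptors, 2.15 for Hox, 1.32 for Rhox, Xlr and Mage, 1.01 for histone, 1.06 for foregut regulators (0.343 in replicate 1), 1.25 for stomach products (0.280 in replicate 1) and 0.596 for repressive chromatin. In the pooled list it was 1.27 for olfactory receptors, 1.61 for beta-defensin and urinary protein, 1.59 for histone and 0.796 for repressive chromatin genes. Within 2 kb of transcription starts it was 0 for vomeronasal, neural and repressive chromatin genes. With 10 kb on both sides of genes it was 1.15 for beta-defensin and urinary protein, 1.23 for foregut regulators, 1.01 for muscle, blood and immune and 1.57 for liver, pancreas and intestine genes. In the alternative with Fisher's exact test, the share of foregut regulators overlapped was 1.05 times that of other genes. Depth limits single peaks, since the median replicate summit held 11 or 10 fragments.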

Other observations

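Of the tests in this part, those on q-values and on control rates in the block of chromosome 1, and the test of gene families, were chosen after the results they measure were seen. Peaks in zinc finger genes lay in the exon that ends the coding sequence more often than random points did. Of 174 replicated peaks in these genes, 82 had their midpoint in that exon, or 47.1% (95% exact interval 39.5 to 54.8). Points placed at random in the same gene windows did so in 14.3% of cases, a ratio of 3.30 (two-sided permutation p = 0.000200, the smallest that 10000 draws can give). This was predicted as a hypothesis before it was measured, since the finger arrays of such genes commonly lie in that exon, though some strong peaks, as in Zfp37, had already been seen to lie on coding exons. In other protein-coding genes the share was 9.37%, against 4.81% at random, a ratio of 1.95. Whether the ratios differ was not tested. The random points and the exact interval treat peaks as independent, but 38 of the 69 overlapped zinc finger genes held 2 or more. Unlike the shifts used for gene lists, the random points do not keep the spacing of peaks. The interval may therefore be too narrow and the evidence overstated.

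Gene families formed by the stem of the symbol were tested without a fixed list, and the genes named here were picked out by that test. A first run used 1000 shifts, too few for any of so many families to pass, and the number was then raised to 20000, of which the smallest p is 0.0001. Of 281 families with 10 or more genes, 1 passed adjustment, Zfp, with 69 of 394 genes against a shifted mean of 7.73 (permutation p = 0.0001, adjusted p = 0.0281). These are the 69 genes already overlapped in the fixed zinc finger list, on the same peaks, so the result is not separate support. The secretoglobin genes Scgb came next with 4 of 34 against 0.176 (permutation p = 0.00110, adjusted p = 0.155). These were Scgb2b2, Scgb1b2, Scgb1b3 and Scgb1b24 on chromosome 7, with a median fold of 2.89 and a control rate of 6.05. The 9 overlapped Ugt genes were those of the chromosome 1 block (permutation, adjusted p = 0.955).

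The small overlap of the replicates was weighed against 3 technical explanations. If each replicate 1 peak were a site of its measured fold, counting noise at the depth of replicate 2 would let 71.8% pass there, against the 9.72% observed, so noise around the measured folds does not account for it. Folds of selected peaks overstate the sites, and weaker sites stay open: with a fold of 1.5 at every site, 8.88% would pass. Replicate 1 peaks with a q-value of 0.05 or less overlapped replicate 2 in 26.0% of cases and the others in 8.17%, a ratio of 3.19. Chance peaks let in by a permissive threshold and weaker real sites would both give such a ratio. The median −log10 q was 0.173 in replicate 1 and 0.149 in replicate 2. By the caller's own q-values, many chance peaks are therefore to be expected in both lists. The 8.17% is above the 0.386% of shifted peaks, so some of the peaks with a larger q-value are not chance. How the rest divide between chance peaks and weaker real sites was left open. A different GC bias of the libraries was not excluded, since 15.0% of replicate 1 peaks in the highest of 3 equal groups by GC were shared and 5.95% in the lowest, a ratio of 2.51. Shared peaks had a mean GC share of 46.3% in replicate 1 and 46.7% in replicate 2. The other peaks had 43.2% in replicate 1 and 46.6% in replicate 2, so the lists differed in GC mainly in the peaks they did not share. A GC bias that differs between the libraries could give this. How far it lowers the overlap was not tested. No biological explanation was tested, because the design has 1 group.

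The block of 39 replicated peaks within 99.3 kb on chromosome 1 stood on a raised control rate. The median control rate of the 40 replicated peaks in its window was 5.83 times the commonest rate, and pooled peaks outside the block between 87 and 90 Mb had a median rate of 6.25. The tables argue against reads shared between copies that the reference holds, since the median peak had 0% of its 32-base words again on the assembled chromosomes. A candidate explanation is that animals of strain B6NCrl carry extra copies of this block that the reference lacks. The lists hold no direct measure of copy number, and scaffolds were not searched, so this stays a hypothesis. The other blocks of 9 or more peaks at a high control rate differed in how much of their sequence is repeated. Medians of repeated 32-base words were 17.8% at chromosome 13, 119596925 to 119617704 (10 peaks, 12 times the commonest rate), and 5.41% at chromosome 11, 3184240 to 3200073, at Drg1 and Sfi1 (9 peaks, 31.4 times). They were 79.9% at chromosome 9, 2999916 to 3036581 (9 peaks, 17.6 times), and 100% at chromosome X, 169980806 to 170022365, at Mid1 (9 peaks, 4.70 times). Only occurrences were counted, and where the other copies of these words lie was not recorded.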
